A study of Homo sapiens with 16 samples.

How the data were processed

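Total RNA of HUH6 cells, an established human hepatoblastoma line, was sequenced in 16 libraries, 4 in each of 4 groups formed by compound (DMSO or 100 µM SLC-0111) and oxygen (normoxia or hypoxia with 1%). Cells were grown in DMEM with fetal bovine serum, treated for 48 h and lysed for column purification of total RNA, per the labels' protocols. The groups and replicate numbers were taken from the sample labels, which call the replicates technical. Of the columns of the deposited table, 2 have names that conflict with the sample labels: 1 in normoxia SLC-0111 and 1 in hypoxia DMSO. Each repeats the replicate number of another column of its group, 4 and 1, while its library number is that of replicate 2 and 4 in the labels. The names agree on the group but not on the replicate, so these libraries were given no replicate number and are called unnumbered. No column was left out.

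The deposited values are raw counts of reads per gene. Reads were aligned with HISAT2 (also written HISAT) to GRCh38, counted with HTSeq and checked with MultiQC 1.10.1, and edgeR 3.4.0 was used for the differential test, per the submitters' processing notes. The notes give no version of the aligner or counter, and the strand setting of the count was not given in the sources used here. Genes that overlap on opposite strands may therefore share reads. Members of near-identical families (metallothioneins, AKR1C enzymes, HSPA1 proteins, histones) may exchange reads as well. The table holds 58735 genes, and the identifier, start, end and strand of each were found in GENCODE release 29, which gave gene types and the coordinates printed here.

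Total counts summed to 430.7 M (M is 1000000 counts). They were 22.91, 25.17, 30.08 and 31.60 M in normoxia DMSO replicates 1 to 4, and 21.60, 28.24, 40.09 and 21.92 M in normoxia SLC-0111 replicates 1, 3, 4 and the unnumbered library. In hypoxia they were 23.92, 32.88, 3.30 and 18.28 M with DMSO (1, 2, 3, unnumbered) and 19.51, 32.88, 29.08 and 49.25 M with SLC-0111 (1 to 4). A count of 0 is compatible with up to 3 reads, which is 0.061 to 0.91 CPM over these depths. MT-RNR2, a mitochondrial ribosomal RNA, had the most counts in every library. Pearson's r between libraries of a group was 0.963 to 0.995. The spread of replicate pairs over counting error, as chi-square per degree of freedom in genes with at least 20 counts, was 2.27 to 73.36, so no library was a copy of another.

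Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (18385 genes), scaled by TMM, and fitted with robust quasi-likelihood dispersion in a model with 1 mean per group, which left 12 residual degrees of freedom. The common biological coefficient of variation was 0.074. Printed log2 fold changes are those of this test, and each SE is the absolute log2 fold change divided by the square root of the F statistic. Log2 CPM for the principal components and the list tests used a prior count of 2. The contrasts were tested: SLC-0111 against DMSO in normoxia and in hypoxia, hypoxia against normoxia with DMSO and with SLC-0111, and the difference of the SLC-0111 effects. A gene was called at an adjusted p (Benjamini and Hochberg) under 0.05. Where a group had few counts, the ratio of group totals is given, each scaled to CPM by total counts without TMM. Its 95% interval covers counting error only.

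In all, 38 gene lists (839 entries, 838 found in the table) were written before the data were examined, as were the groups, the contrasts, the main model, most alternatives and the rule for named genes. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Each list is also given as the number of called members, over all genes and adjusted over the list alone. By the rule, CA9 and CA12 are always named. For the single contrasts, up to 10 largest rises and 10 largest falls are named among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups. For the difference, 6 in each direction are named. Up to 4 called members with at least 1 CPM are named per list. Clones, antisense and small RNAs and pseudogenes were passed over. Some genes that the rule names are not reported here.

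The model was tested on simulated data with 200 genes changed. It recovered 184, 177, 183 and 189 of them in the 4 single contrasts and 161 in the difference, with 11, 4, 9, 12 and 9 other calls. A list changed on purpose was called, and 0 of the others were. The genes were simulated independently, so this does not test list calls where members vary together. All simulated libraries had the same dispersion per gene, so the numbers of other calls do not cover groups with uneven libraries, such as hypoxia DMSO. Alternatives were RLE scaling, library size alone, no filter, a filter at 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, each library left out in turn, and a replicate block on the 14 numbered libraries. Added after the data were seen were the protein-coding share as a covariate, nuclear protein-coding genes only, the 14 numbered libraries without the block, and each pair of hypoxia DMSO libraries left out. Other splits of the libraries into groups of the same size were run for each contrast.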

Results

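The series measured total RNA by sequencing in HUH6 cells, an established human hepatoblastoma line, after 48 h of culture. The cells received DMSO, the solvent control, or 100 µM SLC-0111 (also U-104), which the labels describe as an inhibitor of carbonic anhydrases IX and XII. Both arms were kept either in normoxia or in hypoxia with an oxygen partial pressure of 1%. Each of the 4 groups had 4 libraries, which the labels call technical replicates, so every p-value measures only the spread between such libraries and not that between separate cultures. Total counts per library ran from 3.30 M (M is 1000000) in hypoxia DMSO replicate 3 to 49.25 M in hypoxia SLC-0111 replicate 4, and the next lowest total was 18.28 M. Levels are given as counts per 1000000 counts (CPM) of the library size after TMM scaling, with the SD over the 4 libraries of a group (n = 4). Changes are given as fitted log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test.

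On the first principal component, with 47.9% of the variance, the libraries separated by oxygen. The second, with 18.6%, set hypoxia DMSO replicate 3, the shallowest library, at 96.3, apart from all others. Hypoxia DMSO replicate 1 lay at 27.3 on the first component, while the other hypoxia DMSO libraries lay between 48.2 and 49.6. The protein-coding share of the counts was 89.8% ± 0.82 in normoxia DMSO, 86.5% ± 4.12 in normoxia SLC-0111, 91.5% ± 1.18 in hypoxia DMSO and 90.2% ± 1.56 in hypoxia SLC-0111 (SD, n = 4 each). The lowest share was 80.6%, in normoxia SLC-0111 replicate 4, whose mitochondrial share was 15.3%.

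**Figure D1:**
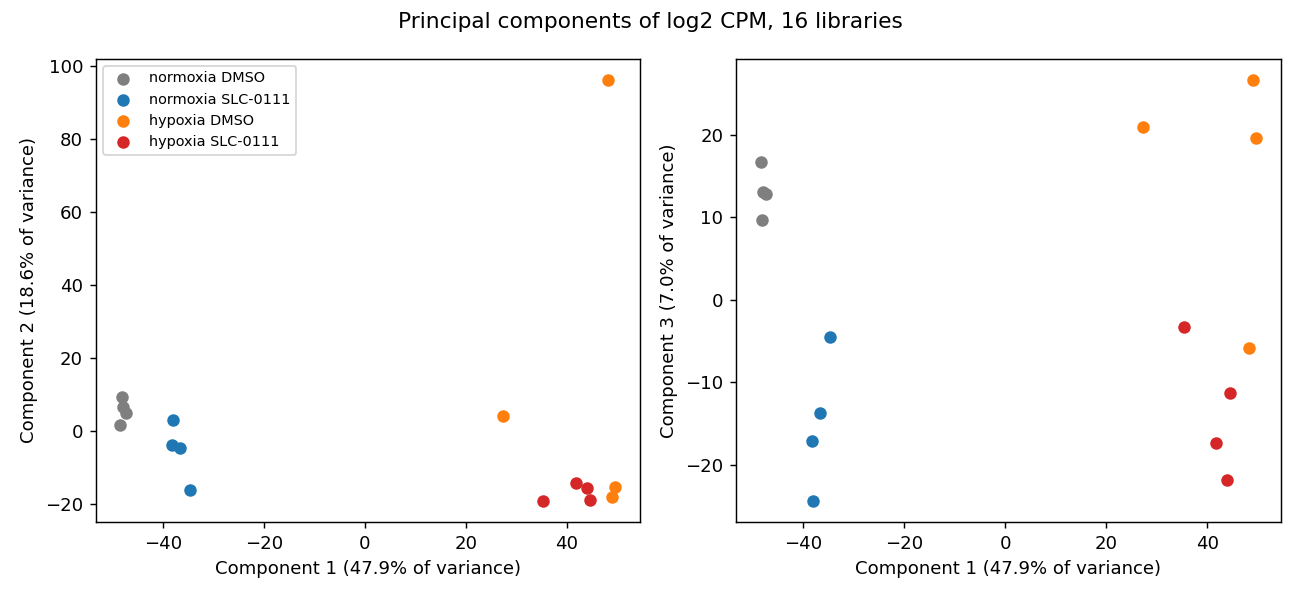
Principal components of log2 CPM over the 16 libraries, component 1 against component 2 (left) and against component 3 (right), with axes in component scores and colours for the 4 groups. Normoxia and hypoxia libraries separate on component 1 (47.9% of the variance), and hypoxia DMSO replicate 3 stands at 96.3 on component 2.

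The genes of the stated targets were read first. CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159, GRCh38) encodes carbonic anhydrase IX, a membrane enzyme that hydrates carbon dioxide outside the cell. It was barely detected in normoxia, with 7 counts over the 4 DMSO libraries and 5 over the 4 SLC-0111 libraries. A difference between these was not detectable at this depth, and no fold is given. In hypoxia, CA9 reached 56.2 ± 7.55 CPM with DMSO and 26.6 ± 2.90 CPM with SLC-0111 (SD, n = 4 each). It therefore fell with the compound in hypoxia, at log2 −1.08 ± 0.10 (adjusted p = 2.1e-07). CA12 (ENSG00000074410, chromosome 15, 63321378 to 63382161), the gene of carbonic anhydrase XII, stood at 2.66 ± 0.393 CPM in normoxia DMSO. With SLC-0111 in normoxia it rose to 5.05 ± 0.359 CPM (log2 0.91 ± 0.12, adjusted p = 6.11e-06). In hypoxia it stood at 5.97 ± 0.612 CPM with DMSO and 6.03 ± 0.630 CPM with SLC-0111, and that difference did not pass the test (adjusted p = 0.882). The effect of SLC-0111 on CA12 differed between the oxygen conditions, by log2 −0.95 ± 0.17 (adjusted p = 0.00127). CA4, a membrane-anchored carbonic anhydrase, fell in normoxia from 16.3 ± 1.18 to 8.63 ± 0.723 CPM (log2 −0.92 ± 0.09, adjusted p = 8.89e-08), and CA2, a cytosolic one, rose in hypoxia from 12.8 ± 0.629 to 19.7 ± 1.06 CPM (log2 0.61 ± 0.11, adjusted p = 0.000252).

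**Figure D2:**
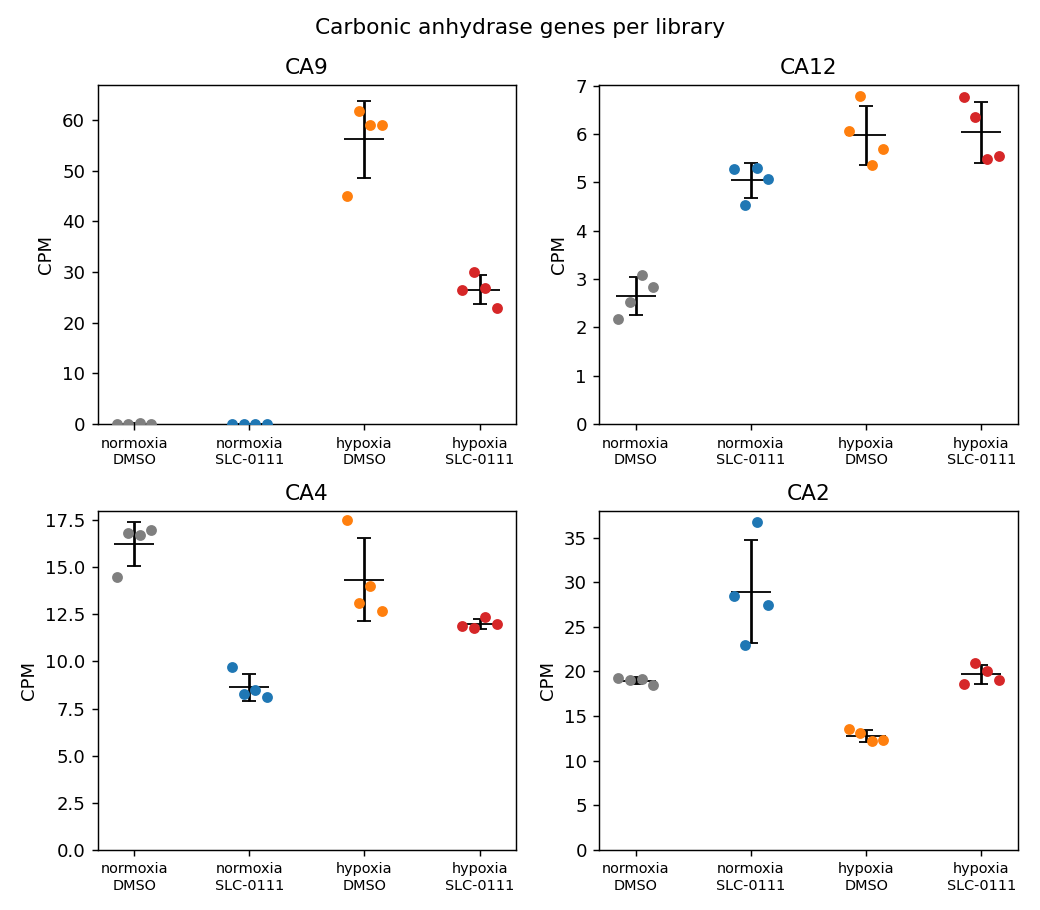
CPM of CA9, CA12, CA4 and CA2 in each library, with the group mean (bar) and SD (whiskers, n = 4). The CA9 mean was 56.2 CPM in hypoxia DMSO and 26.6 CPM in hypoxia SLC-0111, and CA12 was lowest in normoxia DMSO, at 2.66 CPM.

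Of the 12 tested members of the carbonic anhydrase list, 4 were higher and 2 lower with SLC-0111 in normoxia, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.155). In hypoxia 2 were higher and 1 lower, or 3 and 2 adjusted over the list alone (adjusted p = 0.912). The 16 tested genes of acid-base and bicarbonate transport held 3 higher and 4 lower in normoxia, or 5 and 4 adjusted over the list alone. Their median and mean were above 0 (log2 0.11 and 0.10) while camera's direction was down, with adjusted p = 0.872. In hypoxia 1 was higher and 2 were lower, with the same counts adjusted over the list alone, a median of log2 −0.06, a mean of 0.03 and adjusted p = 0.809.

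SLC-0111 against DMSO in normoxia. This comparison asks what the compound did to the transcriptome with oxygen present. Of 32 ATF4 and amino acid response genes 22 were higher, while 25 of 30 mitosis genes, 23 of 32 DNA replication genes and 21 of 26 ribosome biogenesis genes were lower. None of these lists was called with an estimated correlation (adjusted p = 0.0697, 0.0968, 0.232 and 0.128). SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349), the light chain of the cystine and glutamate exchanger, had the largest rise under the rule for named genes, from 19.6 ± 1.07 to 61.2 ± 5.25 CPM (log2 1.65 ± 0.07, adjusted p = 4.8e-14). CHAC1, which degrades glutathione, rose from 1.80 ± 0.164 to 5.23 ± 0.574 CPM (log2 1.55 ± 0.15, adjusted p = 9.31e-08). Nuclear receptor gene NR1I3 (CAR) rose by log2 1.62 ± 0.17 (adjusted p = 4.17e-07), and CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, went from 46.8 ± 3.17 to 125.2 ± 6.62 CPM (log2 1.42 ± 0.07, adjusted p = 2.95e-13). The hyaluronan synthase gene HAS3 had the largest fall under the rule, from 26.8 ± 0.880 to 11.4 ± 0.881 CPM (log2 −1.25 ± 0.14, adjusted p = 3.5e-06).

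Other large rises in normoxia were PADI2 (log2 1.59), GPRC5A (1.54), PGLYRP2 (1.52), ABI3BP (1.45) and FLNC (1.42), the last of them an abundant actin crosslinker at 178.4 ± 10.1 CPM in DMSO and 476.9 ± 50.1 CPM with SLC-0111 (adjusted p = 2.08e-06). NPPB, which encodes a natriuretic peptide, rose from 3.67 ± 0.487 to 10.4 ± 1.44 CPM (log2 1.53 ± 0.42, adjusted p = 0.0185), but its adjusted p was 0.05 without normoxia DMSO replicate 4, 0.0579 without normoxia SLC-0111 replicate 4, 0.105 in limma-voom and 0.091 with the protein-coding share as a covariate. Large falls were FOXJ1 (log2 −1.21), DNAH10 (−1.10) and KIF26A (−1.02). FOXJ1 is a transcription factor of motile cilia and DNAH10 a dynein heavy chain of their axoneme. GPR161 fell from 159.0 ± 3.23 to 80.8 ± 3.95 CPM (log2 −0.98 ± 0.06, adjusted p = 2.86e-11), TGFB3 by log2 −0.95 and the carboxypeptidase gene CPB2 by log2 −0.88.

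The list of ATF4 targets and amino acid response genes had 22 of 32 tested members higher and 0 lower, with the same counts adjusted over the list alone, and a median of log2 0.58 (camera adjusted p = 1.46e-21, and adjusted p = 0.0697 with an estimated correlation). Of the 25 tested NRF2 targets, which answer oxidative stress, 14 were higher and 1 was lower in both counts (adjusted p = 3.18e-07, and adjusted p = 0.0697 with an estimated correlation). ABCC3, an efflux transporter on that list, rose from 5.45 ± 0.568 to 12.3 ± 0.872 CPM (adjusted p = 1.27e-09). Of 11 metallothionein and zinc transport genes, 4 rose and 0 fell, or 6 and 0 adjusted over the list alone (adjusted p = 0.00096, and adjusted p = 0.0968 with an estimated correlation). MT2A rose from 21.7 ± 1.69 to 44.0 ± 3.28 CPM and MT1G from 2.82 ± 0.358 to 6.41 ± 1.07 CPM, although metallothionein genes are near-identical copies between which reads may have been split. Among 23 hepatocyte metabolic enzymes 9 rose and 0 fell, or 11 and 0 adjusted over the list alone (adjusted p = 2.85e-07, and adjusted p = 0.0968 with an estimated correlation). HPD, a tyrosine-degrading enzyme, rose from 21.4 ± 1.03 to 34.8 ± 2.50 CPM, and the urea cycle gene OTC from 0.444 ± 0.0249 to 1.06 ± 0.194 CPM. Of 20 collagen and matrix genes 11 rose and 1 fell, or 11 and 2 adjusted over the list alone (adjusted p = 7.9e-06, and adjusted p = 0.262 with an estimated correlation). COL1A1 was at 10.5 ± 0.417 CPM in DMSO and 19.7 ± 3.65 CPM with SLC-0111, where replicate 4, the library with the lowest protein-coding share, stood at 25.2 CPM. P4HA1, a collagen prolyl hydroxylase, rose from 137.0 ± 2.84 to 210.6 ± 20.7 CPM.

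In the opposite direction, 25 of 30 mitosis and G2/M genes were lower and 0 higher, or 27 and 0 adjusted over the list alone (camera adjusted p = 1.28e-17, and adjusted p = 0.0968 with an estimated correlation). The mitotic kinase gene PLK1 fell from 89.8 ± 3.30 to 63.4 ± 3.36 CPM (log2 −0.50 ± 0.06, adjusted p = 7.21e-07) and BIRC5 (survivin) from 110.6 ± 3.73 to 80.3 ± 3.56 CPM. Of 32 DNA replication and S phase genes 23 were lower and 0 higher, or 27 and 0 adjusted over the list alone (adjusted p = 2.12e-13, and adjusted p = 0.232 with an estimated correlation). FEN1, a flap endonuclease, fell by log2 −0.50 and GINS2, part of the replicative helicase, by log2 −0.49. Ribosome biogenesis had 21 of 26 lower and 0 higher, or 22 and 0 adjusted over the list alone (adjusted p = 2.64e-11, and adjusted p = 0.128 with an estimated correlation), with NOP16 at log2 −0.49 and MYBBP1A at log2 −0.39. These falls were each less than 2-fold. Heat shock genes had 8 of 15 lower and 0 higher in both counts (adjusted p = 0.000122, and adjusted p = 0.162 with an estimated correlation), including HSPB1, from 148.4 ± 3.55 to 109.7 ± 12.2 CPM. ER chaperones had 12 of 22 lower and 1 higher, or 13 and 3 adjusted over the list alone (adjusted p = 0.00127, and adjusted p = 0.413 with an estimated correlation). SDF2L1, an ER chaperone cofactor, fell from 56.7 ± 4.16 to 32.8 ± 4.42 CPM.

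Glycolysis and glucose uptake genes had 9 of 20 lower and 1 higher in normoxia, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.509 with an estimated correlation). PGAM1 fell from 406.2 ± 10.3 to 286.9 ± 25.9 CPM and PKM from 563.9 ± 20.2 to 433.6 ± 16.3 CPM. Cholesterol synthesis and uptake genes had 7 of 25 lower and 0 higher, or 10 and 0 adjusted over the list alone (adjusted p = 0.00134, and adjusted p = 0.571 with an estimated correlation). With the protein-coding share as a covariate this count was 3 lower and 2 higher, and without normoxia SLC-0111 replicate 4 it was 5 lower and 1 higher.

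In all, 2271 genes were higher and 2067 lower with SLC-0111 in normoxia, 4338 of 18385 tested (23.6%), of which 209 and 55 changed at least 2-fold. With scaling by library size alone the split was 1396 higher and 3141 lower, so the balance of directions depended on the scaling. The 4 libraries of one group lay all above or all below those of the other in 5449 genes (29.6%), against 2.86% for exchangeable libraries. That share takes the technical replicates as independent, so it does not cover differences between cultures. Of 38 lists, 37 had at least 5 tested members, and 18 were called, 8 up and 10 down. With an estimated correlation 0 of them were called, while fry, which does not compare a list with other genes, called 19.

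**Figure D3:**
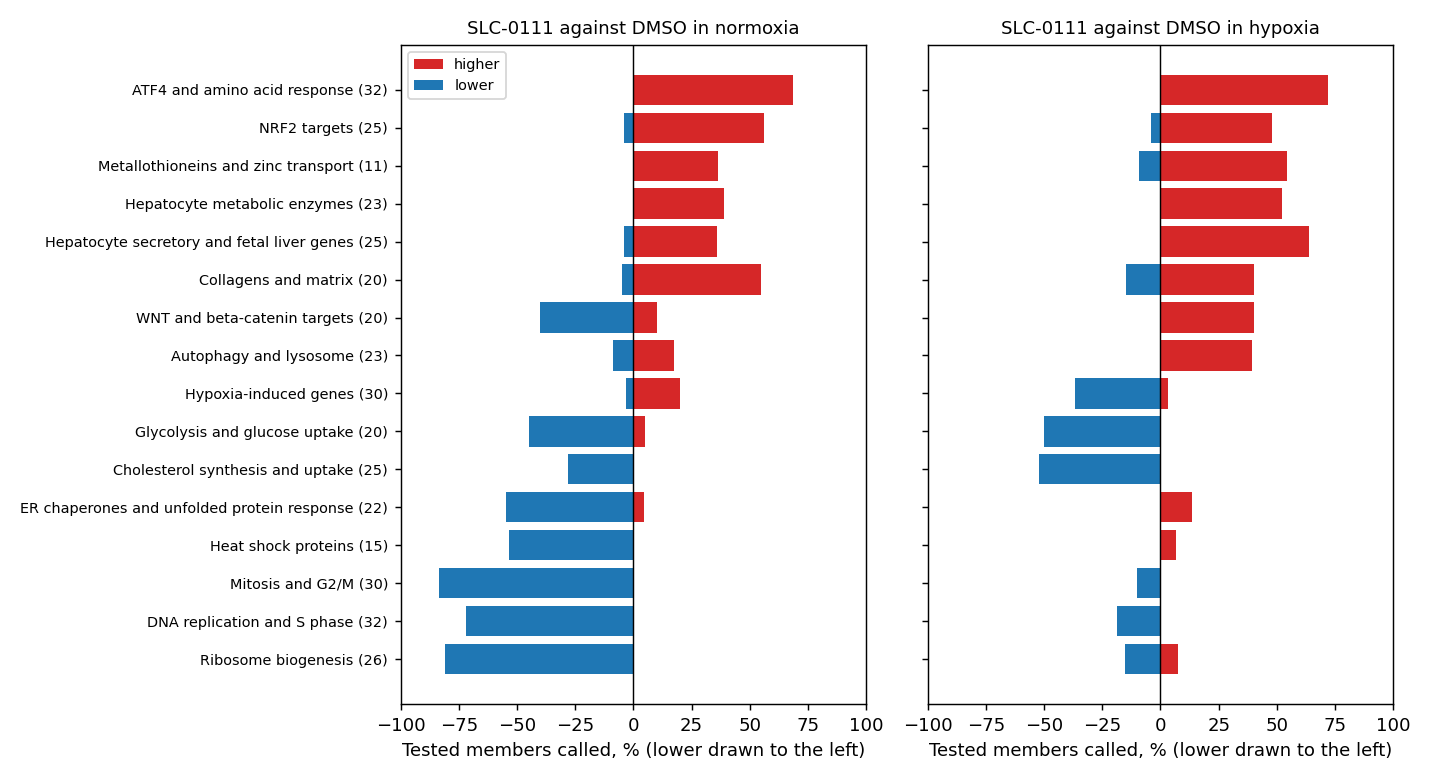
Share of the tested members of 16 gene lists (number tested in brackets) called higher (red, right) or lower (blue, left) with SLC-0111, in percent, in normoxia (left panel) and hypoxia (right panel). In normoxia 25 of 30 mitosis genes were lower, in hypoxia 3 of 30, while the ATF4 list had 22 and 23 of 32 members higher.

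SLC-0111 against DMSO in hypoxia. Here the question is what the compound did at low oxygen. CA9 was lower, as were 11 of 30 hypoxia-induced genes, 10 of 20 glycolysis genes and 13 of 25 cholesterol genes, and none of these lists was called with an estimated correlation (adjusted p = 0.506, 0.145 and 0.357). Higher were 23 of 32 ATF4 and amino acid response genes and 16 of 25 hepatocyte secretory genes, lists that were not called with an estimated correlation either (adjusted p = 0.0688 and 0.201). STC1 (ENSG00000159167), a secreted glycoprotein, went from 21.9 ± 4.69 to 8.25 ± 0.835 CPM (log2 −1.38 ± 0.13, adjusted p = 1.51e-07). The largest fall under the rule was RNF223, from 7.43 ± 1.59 to 2.72 ± 0.468 CPM (log2 −1.41 ± 0.16, adjusted p = 1.12e-06), and B3GNT4, a glycosyltransferase, fell by log2 −1.38. MAB21L3 fell from 67.5 ± 1.81 to 32.3 ± 4.52 CPM (adjusted p = 1.12e-09), WDR54 from 31.1 ± 0.914 to 15.4 ± 0.391 CPM (adjusted p = 7.96e-11) and RNF183 from 18.7 ± 0.798 to 8.92 ± 1.11 CPM. SYDE1 fell by log2 −1.09, and the collagen chain COL1A2 fell from 19.5 ± 0.767 to 9.66 ± 1.31 CPM (adjusted p = 4.34e-07).

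Under the rule the largest rises in hypoxia were MT1G and GCM1. MT1G rose from 3.51 ± 0.516 to 10.3 ± 1.14 CPM (log2 1.52 ± 0.14, adjusted p = 4.44e-08). GCM1, a transcription factor known from the placenta, rose from 9.06 ± 1.37 to 27.1 ± 2.95 CPM (log2 1.52 ± 0.09, adjusted p = 7.96e-11). SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 1.89 ± 0.64 to 5.81 ± 0.952 CPM, the organic anion transporter SLC22A7 by log2 1.42, NR1I3 by 1.31 and ST3GAL1 by 1.23. CYP1A1 went from 28.6 ± 3.16 to 68.2 ± 5.75 CPM (log2 1.21 ± 0.07, adjusted p = 7.96e-11), and NR1D1, a circadian repressor, from 10.5 ± 3.58 to 26.1 ± 5.22 CPM (log2 1.25 ± 0.20, adjusted p = 0.000516). ANKRD1 was at 116.5 ± 62.6 CPM with DMSO and 269.0 ± 53.4 CPM with SLC-0111 (log2 1.16 ± 0.32, adjusted p = 0.0252). Its adjusted p was 0.0599 without hypoxia DMSO replicate 3, and 0.0672, 0.0548 and 0.063 without hypoxia SLC-0111 replicates 1, 2 and 3. With only the groups compared in the fit it was 0.152.

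The ATF4 and amino acid list had 23 of 32 members higher and 0 lower in hypoxia, or 25 and 0 adjusted over the list alone (camera adjusted p = 4.38e-19, and adjusted p = 0.0688 with an estimated correlation). CHAC1 rose from 1.48 ± 0.197 to 3.52 ± 0.864 CPM, and SLC7A11 from 17.0 ± 1.83 to 35.6 ± 2.35 CPM (adjusted p = 1.78e-09). NRF2 targets had 12 of 25 higher and 1 lower, or 14 and 2 adjusted over the list alone (adjusted p = 2.97e-05, and adjusted p = 0.0909 with an estimated correlation). Under scaling by library size alone that count was 7 higher and 2 lower. Metallothionein and zinc transport genes had 6 of 11 higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 2.97e-05, and adjusted p = 0.0688 with an estimated correlation). MT1F rose from 19.5 ± 3.30 to 40.3 ± 3.33 CPM, with the same limit of near-identical copies. Hepatocyte secretory and fetal liver genes had 16 of 25 higher and 0 lower, or 18 and 0 adjusted over the list alone (adjusted p = 2.41e-09, and adjusted p = 0.201 with an estimated correlation). APOH, a plasma glycoprotein, rose from 4.55 ± 0.258 to 7.68 ± 0.289 CPM. In normoxia the same list had 9 higher and 1 lower, or 12 and 2 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.578 with an estimated correlation), with APOC3, an apolipoprotein, rising from 125.9 ± 2.60 to 224.2 ± 23.7 CPM. Hepatocyte metabolic enzymes had 12 of 23 higher and 0 lower, or 14 and 1 adjusted over the list alone (adjusted p = 2.41e-09, and adjusted p = 0.0688 with an estimated correlation), HPD rising from 29.6 ± 1.32 to 45.7 ± 2.33 CPM.

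WNT and beta-catenin targets had 8 of 20 higher and 0 lower in hypoxia, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.16e-06, and adjusted p = 0.145 with an estimated correlation). By library size alone 5 were higher. In normoxia 2 of the 20 were higher and 8 lower, or 3 and 8 adjusted over the list alone, with a median of log2 −0.16, and the list was not called (adjusted p = 0.0675). Without normoxia SLC-0111 replicate 4 these counts were 3 and 5 with a median of log2 −0.05, and with the protein-coding share as a covariate 2 and 5 with a median of 0. LGR5, a WNT-responsive stem cell marker, rose from 35.1 ± 2.00 to 58.4 ± 2.38 CPM and TBX3 from 572.5 ± 128 to 862.2 ± 73.9 CPM. Autophagy and lysosome genes had 9 of 23 higher and 0 lower, or 13 and 0 adjusted over the list alone (adjusted p = 1.9e-07, and adjusted p = 0.101 with an estimated correlation). The lysosomal protease gene CTSL rose from 130.8 ± 10.2 to 201.7 ± 17.4 CPM and the autophagy receptor gene SQSTM1 from 130.5 ± 5.77 to 190.7 ± 18.5 CPM. Of the 13 mitochondrially encoded respiratory chain genes 5 were higher and 0 lower, or 10 and 0 adjusted over the list alone (adjusted p = 6.87e-07, and adjusted p = 0.351 with an estimated correlation), and without hypoxia DMSO replicate 1 the count was 9. MT-ND4 rose from 1734 ± 175 to 2859 ± 596 CPM, while the mitochondrial share of all counts was 6.31% ± 0.55 with DMSO and 7.67% ± 1.02 with SLC-0111 (SD, n = 4 each).

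Of 30 hypoxia-induced genes 11 were lower and 1 was higher with SLC-0111 in hypoxia, or 13 and 1 adjusted over the list alone (camera adjusted p = 8.91e-05, and adjusted p = 0.506 with an estimated correlation). The median was log2 −0.228. HILPDA, a lipid droplet protein, fell from 40.9 ± 6.56 to 22.8 ± 2.47 CPM (adjusted p = 4.52e-07), whereas P4HA1 rose from 276.0 ± 16.3 to 350.7 ± 8.97 CPM. This list depended on the hypoxia DMSO libraries, which stood apart from each other: without replicate 1, 18 members were lower, and without replicate 2 together with the unnumbered library the median was log2 0.053 with 9 lower. Glycolysis and glucose uptake genes had 10 of 20 lower and 0 higher, or 12 and 0 adjusted over the list alone (adjusted p = 6.48e-07, and adjusted p = 0.145 with an estimated correlation). PGK1 fell from 1187 ± 61.2 to 811.8 ± 32.0 CPM (adjusted p = 7.08e-08). Cholesterol synthesis and uptake genes had 13 of 25 lower and 0 higher, or 15 and 0 adjusted over the list alone (adjusted p = 3.51e-09, and adjusted p = 0.357 with an estimated correlation). CYP51A1, a sterol demethylase, fell from 15.6 ± 1.39 to 10.8 ± 1.14 CPM.

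Mitosis and G2/M genes had 3 of 30 lower and 0 higher in hypoxia, with the same counts adjusted over the list alone (camera adjusted p = 0.00429, and adjusted p = 0.513 with an estimated correlation). DNA replication genes had 6 of 32 lower and 0 higher, or 7 and 0 adjusted over the list alone (adjusted p = 7.63e-05, and adjusted p = 0.506 with an estimated correlation). Without hypoxia DMSO replicate 1 each of these lists had 1 lower and 1 higher, and by library size alone they had 5 and 11 lower. In all, 1681 genes were higher and 1307 lower with SLC-0111 in hypoxia, 2988 of 18385 (16.3%), of which 65 and 136 changed at least 2-fold. With scaling by library size alone 959 were higher and 1941 lower, and with only the groups compared in the fit 1972 genes were called. Groups did not overlap in 3132 genes (17.0%), against 2.86% for exchangeable libraries. Of 37 lists 23 were called, 16 up and 7 down, and 0 with an estimated correlation, against 21 by fry.

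The effects of SLC-0111 in the 2 oxygen conditions, which share no library, were then set side by side. Called in the same direction in both were 1320 genes, 883 higher and 437 lower, where independent lists of these sizes would share 207.6 and 146.9. Both contrasts came from the same fit with a shared dispersion per gene, so genes with little spread are called more readily in both. The expected numbers make no allowance for that. Called in opposite directions were 83 genes. Across the 18385 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.314 and Spearman's rho 0.321, and r was 0.505 over the 10770 genes with a mean of at least 5 CPM.

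**Figure D4:**
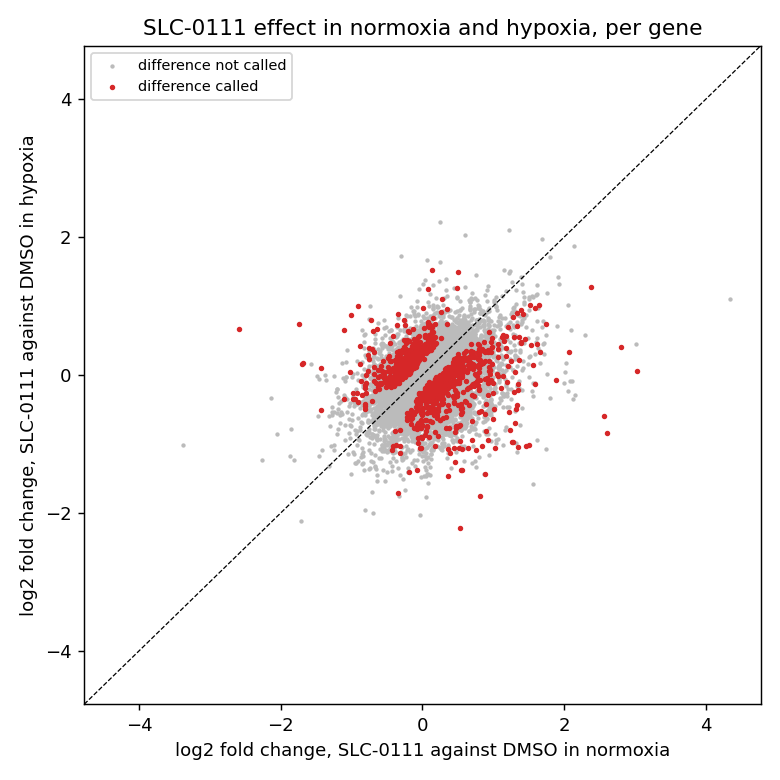
Fitted log2 fold change with SLC-0111 of each of 18385 genes in normoxia (horizontal axis) and hypoxia (vertical axis), with the line of equal effects (dashed). Red points are the 1102 genes whose effect differed between the oxygen conditions, and Pearson's r across genes was 0.314.

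Difference of the SLC-0111 effect between hypoxia and normoxia. The test of the difference itself asks which responses to the compound depended on oxygen. TNFSF10, which encodes the death ligand TRAIL, had the most negative difference under the rule, at log2 −1.77 ± 0.15 (adjusted p = 2.53e-07). Its level went from 2.47 ± 0.348 to 6.16 ± 0.247 CPM with SLC-0111 in normoxia and from 78.9 ± 10.4 to 59.0 ± 5.47 CPM in hypoxia. The water channel gene AQP1 went from 6.68 ± 1.08 to 11.8 ± 1.44 CPM in normoxia and from 114.7 ± 9.60 to 79.3 ± 3.89 CPM in hypoxia (difference log2 −1.35 ± 0.13, adjusted p = 1.59e-06). NREP (log2 −1.64) and PLEKHA2 (−1.37) also had negative differences, PLEKHA2 with adjusted p = 0.0125 in edgeR and 0.0701 in limma-voom. Positive differences were found for EPB41L3 (log2 1.53 ± 0.21, adjusted p = 0.000129), GCM1 (1.38 ± 0.12, adjusted p = 4.32e-07), CPB2 (1.30 ± 0.14, adjusted p = 1.29e-05) and the orphan receptor gene GPR83 (1.05 ± 0.11, adjusted p = 1.92e-06). NR1D1 had log2 1.18 ± 0.29 (adjusted p = 0.0278), which was not called without normoxia DMSO replicate 1 (0.0588), 2 (0.0563) or 4 (0.0603), normoxia SLC-0111 replicate 4 (0.075) or the unnumbered library (0.051), or hypoxia SLC-0111 replicate 1 (0.0548), nor with the protein-coding share as a covariate (0.0755) or no filter on low counts (0.0686). Without the hypoxia DMSO pair 2 and 3 the adjusted p of NR1D1 was 0.0556. GCM1 was at 13.8 ± 0.481 CPM with DMSO and 15.2 ± 0.420 CPM with SLC-0111 in normoxia.

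Among the lists, 11 of 30 hypoxia-induced genes had a negative difference and 0 a positive one, or 18 and 0 adjusted over the list alone (camera adjusted p = 2.67e-10, and adjusted p = 0.357 with an estimated correlation). STC2, a stress-responsive glycoprotein, was among them, at a difference of log2 −1 ± 0.15. The count of negative differences on this list was 20 without hypoxia DMSO replicate 1. It was 10 with RLE scaling, 10 by library size alone and 8 with the protein-coding share as a covariate. Mitosis and G2/M genes had 9 of 30 positive and 0 negative differences, or 16 and 0 adjusted over the list alone (adjusted p = 2.67e-10, and adjusted p = 0.311 with an estimated correlation), PLK1 at log2 0.38 ± 0.08. This count was 3 by library size alone, 17 without hypoxia DMSO replicate 1 and 6 without normoxia SLC-0111 replicate 4. The call of PLK1 was lost without the hypoxia DMSO pair 2 and 3 (adjusted p = 0.0528). WNT targets had 7 of 20 positive and 0 negative, or 10 and 0 adjusted over the list alone (adjusted p = 6.72e-10, and adjusted p = 0.274 with an estimated correlation), including LGR5 at log2 0.63 and NOTUM, a secreted WNT inhibitor, at log2 0.75. The median effect on this list was log2 −0.16 in normoxia and 0.19 in hypoxia, but in normoxia it was −0.05 without SLC-0111 replicate 4 and 0 with the protein-coding share as a covariate, and 6 differences were then positive in either fit. The ATF4 list had 7 of 32 negative and 0 positive, or 9 and 2 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.51 with an estimated correlation), with ALDH1L2, a mitochondrial folate enzyme, at log2 −0.81. SLC7A11, at log2 −0.63 ± 0.10 (adjusted p = 0.000485), rose in both conditions but by less in hypoxia.

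ER chaperones had 4 of 22 positive differences and 0 negative, or 11 and 1 adjusted over the list alone (camera adjusted p = 4.96e-05, and adjusted p = 0.34 with an estimated correlation), with 11 positive without hypoxia DMSO replicate 1. HYOU1 and PDIA4, chaperones of the ER, each had a difference of log2 0.46. In total 527 differences were positive and 575 negative, 1102 genes (6% of those tested). Of these, 711 had fitted effects of opposite sign, but only 83 were called in both conditions with opposite signs. Another 274 had the same sign with the larger effect in normoxia, and 117 had the same sign with the larger effect in hypoxia. The count of 1102 depended on the libraries: it was 2040 without hypoxia DMSO replicate 1, 691 without normoxia DMSO replicate 2 and 708 without hypoxia SLC-0111 replicate 3. Of 37 lists 19 were called, 15 up and 4 down, and 0 with an estimated correlation, against 8 by fry.

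Hypoxia against normoxia in DMSO. This comparison gives the response of the line to low oxygen without the compound. Higher were 29 of 30 hypoxia-induced and 19 of 20 glycolysis genes, and lower were 13 of 13 mitochondrially encoded, 24 of 26 ribosome biogenesis and 21 of 25 cholesterol genes. With an estimated correlation only the glycolysis list was called (adjusted p = 0.026), against 0.15, 0.39, 0.22 and 0.524 for the others. Over the group totals CA9 was 881 times higher in CPM (427 to 2190, a counting interval, as are the others here). GABRA2, a GABA receptor subunit with 2 counts in normoxia DMSO, had a ratio of 1280 (354 to 10600), AQP10 668 (363 to 1390), STC1 478 (205 to 1480), PNCK 374 (203 to 780) and ERBB4, with 3 counts in normoxia, 276 (94.1 to 1340). These intervals cover counting error only. FGD5 rose by log2 6.33 ± 0.19, GNRH2 by 5.63 ± 0.10 and LGI4 by 5.36 ± 0.11. CA12 rose by log2 1.19 ± 0.12 (adjusted p = 2.44e-08), and CA2 fell by log2 −0.55 ± 0.11.

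HAS3 had the largest fall under the rule, from 26.8 ± 0.880 to 2.97 ± 1.52 CPM (log2 −3.09 ± 0.18, adjusted p = 4.8e-11). Other large falls were EPB41L3 (log2 −2.41), SGK1 (−2.06), THBS1 (−2.04), GPAM (−2.03), SOX18 (−1.90) and HSD17B2 (−1.87). THBS1, which encodes thrombospondin 1, went from 212.3 ± 2.73 to 50.9 ± 6.48 CPM. GPAM, which starts glycerolipid synthesis, went from 129.9 ± 4.11 to 32.1 ± 3.75 CPM.

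Of 30 hypoxia-induced genes 29 were higher and 0 lower, with the same counts adjusted over the list alone and a median of log2 2.34 (camera adjusted p = 3.59e-29, and adjusted p = 0.15 with an estimated correlation). Glycolysis genes had 19 of 20 higher and 1 lower in both counts, and this call held with an estimated correlation (adjusted p = 5.51e-21, and adjusted p = 0.026). PDK1, whose product inhibits pyruvate dehydrogenase, rose from 10.4 ± 0.433 to 291.0 ± 55.9 CPM and the glucose transporter gene SLC2A1 from 66.8 ± 2.10 to 864.1 ± 212 CPM. The lower member was PFKM, at log2 −0.15 ± 0.06 (adjusted p = 0.0266). Its call was lost without normoxia DMSO replicate 2 (0.0546) or 3 (0.0757), without hypoxia DMSO replicate 2 (0.0889) or the unnumbered library (0.126), and without hypoxia SLC-0111 replicate 2 (0.0555). The call was also lost with only the groups compared (0.0659), on the 14 numbered libraries (0.139) and with the replicate block on these (0.0905). So it was without each hypoxia DMSO pair except 1 and 3. Collagen and matrix genes had 15 of 20 higher and 3 lower in both counts (adjusted p = 3.56e-05, and adjusted p = 0.39 with an estimated correlation), with the collagen lysyl hydroxylase PLOD2 at log2 3.72 and COL1A2 at log2 2.17. Immediate early genes had 13 of 21 higher and 2 lower in both counts (adjusted p = 0.000451, and adjusted p = 0.508 with an estimated correlation). FOS went from 1.30 ± 0.276 to 39.2 ± 21.2 CPM and JUN from 38.8 ± 2.00 to 442.6 ± 224 CPM, a wide spread between the hypoxia DMSO libraries. All 14 tested replication-dependent histone genes were higher (adjusted p = 6.63e-05, and adjusted p = 0.487 with an estimated correlation), also adjusted over the list alone, HIST1H2BD from 20 ± 2.21 to 43.2 ± 16.1 CPM. Histone genes are near-identical copies, so single members are uncertain.

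All 13 mitochondrially encoded respiratory chain genes were lower in hypoxia, also adjusted over the list alone (camera adjusted p = 1.85e-07, and adjusted p = 0.39 with an estimated correlation). MT-ND2 went from 1669 ± 122 to 518.3 ± 206 CPM and MT-CO3 from 2242 ± 182 to 800.0 ± 243 CPM, and the mitochondrial share of all counts from 8.83% ± 0.36 to 6.31% ± 0.55 (SD, n = 4 each). Nuclear-encoded respiratory chain genes had 21 of 27 lower and 0 higher in both counts (adjusted p = 3.56e-05, and adjusted p = 0.487 with an estimated correlation), SDHB at log2 −0.42. Ribosome biogenesis had 24 of 26 lower and 1 higher in both counts (adjusted p = 6.2e-11, and adjusted p = 0.22 with an estimated correlation). NOP16 and RRS1 each fell by log2 −1.26, and the higher member was FBL, which encodes fibrillarin, at log2 0.39. Cholesterol genes had 21 of 25 lower and 2 higher in both counts (adjusted p = 3.56e-05, and adjusted p = 0.524 with an estimated correlation), MVK at log2 −0.79. Fatty acid synthesis had 15 of 19 lower and 2 higher in both counts (adjusted p = 3.56e-05, and adjusted p = 0.467 with an estimated correlation), ELOVL5 at log2 −0.93.

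ER chaperones had 16 of 22 lower and 3 higher in hypoxia in both counts (camera adjusted p = 3.56e-05, and adjusted p = 0.39 with an estimated correlation), from SDF2L1 at log2 −1.42 to HERPUD1, a factor of ER-associated degradation, at log2 1.06. Heat shock genes had 10 of 15 lower and 1 higher in both counts (adjusted p = 3.56e-05, and adjusted p = 0.22 with an estimated correlation), HSPH1 at log2 −1.26. NRF2 targets had 16 of 25 lower and 5 higher in both counts (adjusted p = 0.00541, and adjusted p = 0.39 with an estimated correlation), with NQO1 at log2 −1.40. Hepatocyte secretory genes went both ways, 7 of 25 higher and 15 lower in both counts (adjusted p = 0.0503): albumin (ALB) fell from 76.8 ± 1.77 to 25.2 ± 2.93 CPM, while transferrin (TF) rose from 1264 ± 24.0 to 2995 ± 194 CPM. In total 4603 genes were higher and 4558 lower, 9161 of 18385 (49.8%), of which 1496 and 321 changed at least 2-fold. Groups did not overlap in 7825 genes (42.6%), against 2.86% for exchangeable libraries. Of 37 lists 17 were called, 5 up and 12 down, 1 with an estimated correlation and 32 by fry.

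Hypoxia against normoxia in SLC-0111. This comparison gives the response to low oxygen in the presence of the compound. CA9 was 564 times higher in CPM over the group totals (241 to 1740), BHLHE40, a transcriptional repressor, rose by log2 4.95 ± 0.27 and FOS by log2 5.60 ± 0.48. HAS3 again had the largest fall under the rule, at log2 −2.37 ± 0.18 (adjusted p = 3.59e-09). CA12 had log2 0.25 ± 0.11 (adjusted p = 0.0667), which did not pass the test. It passed with a stricter filter on low counts (adjusted p = 0.046), with only the groups compared in the fit (0.0496), without hypoxia DMSO replicate 1 (0.0458) and without hypoxia SLC-0111 replicate 4 (0.046). It also passed without the hypoxia DMSO pairs 1 and 2 (0.0448) and 1 and 3 (0.049). Hypoxia-induced genes had 27 of 30 higher and 0 lower, or 28 and 0 adjusted over the list alone (camera adjusted p = 1.26e-28, and adjusted p = 0.159 with an estimated correlation). Glycolysis genes had 18 of 20 higher and 1 lower in both counts (adjusted p = 8.03e-22, and adjusted p = 0.0222 with an estimated correlation), with PDK1 at log2 4.40 and SLC2A1 at log2 3.68. Cholesterol genes had 22 of 25 lower and 0 higher in both counts (adjusted p = 7.31e-09, and adjusted p = 0.458 with an estimated correlation). Ribosome biogenesis had 24 of 26 lower and 1 higher in both counts (adjusted p = 6.68e-08, and adjusted p = 0.353 with an estimated correlation). Of the mitochondrially encoded genes 9 of 13 were lower and 0 higher, or 11 and 0 adjusted over the list alone (adjusted p = 0.00032, and adjusted p = 0.523 with an estimated correlation). The mitochondrial share went from 11.5% ± 2.74 to 7.67% ± 1.02 (SD, n = 4 each).

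With SLC-0111 present, 4398 genes were higher and 4469 lower in hypoxia, 8867 of 18385 (48.2%), of which 1046 and 472 changed at least 2-fold. Groups did not overlap in 8024 genes (43.6%), against 2.86% for exchangeable libraries. Of 37 lists 18 were called, 8 up and 10 down, 1 with an estimated correlation and 28 by fry. Markers of other cell types were measured beside these lists. Of 7 tested fibroblast, endothelial and blood markers, 2 were higher and 1 lower with SLC-0111 in normoxia and 2 higher and 2 lower in hypoxia. In hypoxia against normoxia 4 were higher and 0 lower with DMSO, and 4 higher and 1 lower with SLC-0111. Adjusted over the list alone these counts were 3 and 1, 3 and 2, 4 and 0, and 4 and 1, and camera called the list in none of the 4 comparisons (adjusted p = 0.872, 0.912, 0.0739 and 0.0673). PDGFRB, a receptor of pericytes and fibroblasts, fell with SLC-0111 in both conditions, from 28.6 ± 1.32 to 16.9 ± 0.578 CPM in normoxia and from 54.2 ± 1.31 to 38.5 ± 2.67 CPM in hypoxia. Of 4 tested neural and muscle markers, 2 were higher and 0 lower with SLC-0111 in normoxia, 0 changed in hypoxia, and 1 was higher and 1 lower in hypoxia against normoxia in each arm, with the same counts adjusted over the list alone.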

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

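All tests weighed here were chosen after the result was seen, except the counts of calls under other splits of the libraries, which were planned. A biological explanation was tested only through the groups of the design.

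The first pattern weighed was the fall of 11 of 30 hypoxia-induced genes with SLC-0111 in hypoxia, at a median of log2 −0.228 with all libraries. The hypoxia DMSO libraries were uneven, and over 10 fits leaving out 1 or 2 of them the median ran from −0.422 to 0.053, so this technical explanation stays open for the list. A share of noncoding reads did not account for it as a whole, since the median was −0.199 with the protein-coding share as a covariate. For CA9 itself the value nearest to 0 over the same fits was −0.9, so unevenness did not account for its fall.

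The second pattern was the place of hypoxia DMSO replicate 1 on the first principal component, at 27.3 between normoxia and the other hypoxia DMSO libraries. Mixing with normoxia RNA predicts a uniform fall of hypoxia genes. Over 173 genes high in replicate 2 and the unnumbered library, the median log2 ratio of replicate 1 to these was −0.51. The interquartile range of these ratios was 3.91 times that of replicate 2 against the unnumbered library. These 2 libraries served to pick the genes, and their deviations from the group means correlated (r = 0.449). Other variation in replicate 1 could exceed their spread, so the test cannot exclude mixing. The depth of replicate 1, 23.92 M, lay between that of other libraries of the group. No biological explanation was tested, because the labels give none.

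The third pattern was the rise of amino acid response genes with SLC-0111 in normoxia, at a median of log2 0.58. It was 0.576 with the protein-coding share as a covariate and 0.556 without normoxia SLC-0111 replicate 4, the library with the lowest share, so neither accounts for the rise.

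Under other splits of the libraries, the real grouping gave the most calls in every contrast: 4338 against at most 0 for SLC-0111 in normoxia, 2988 against 257 in hypoxia, 9161 against 6 for hypoxia with DMSO and 8867 against 0 with SLC-0111, each 1 of 35 splits. For the difference it gave 1102 against 616, 1 of 100 splits. Splits that mix the groups carry any real difference into the spread, which lowers their calls, so low counts were likely beforehand. The labels call the libraries technical replicates, so these splits do not speak to differences between cultures.

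A library far from the 3 others of its group, relative to the range of the 4 values, was found in 28 of 508 groups tested. Chance gives about 1 in 20, close to the share found, so single cases carry little weight. The gaps can be small against the level, as for TBX3 and GPR83 in normoxia DMSO. In normoxia DMSO replicate 1, CA4 was at 14.49 CPM (others 16.72 to 16.97), KIF26A 8.011 (9.672 to 9.786), PLK1 94.77 (87.85 to 88.36), APOH 14.32 (15.5 to 15.63), TBX3 280.6 (269.4 to 271.2) and ELOVL5 180 (171.3 to 172.5). Replicate 2 of that group had SPRY4 at 2.533 (1.893 to 1.987) and GPR83 at 18.31 (19.32 to 19.39), replicate 3 had MVK at 99.18 (104.8 to 105.5), and replicate 4 had COL1A1 at 9.875 (10.65 to 10.75), ST3GAL1 at 2.262 (3.493 to 3.622) and HSD17B2 at 59.34 (61.41 to 61.75). Among normoxia SLC-0111 libraries, replicate 3 had HILPDA at 4.208 (4.833 to 4.916), PNCK at 0.2158 (0.07915 to 0.09205) and CENPA at 14.71 (16.48 to 16.75). Replicate 4 had COL1A1 at 25.2 (17.83 to 18.02), CYP51A1 at 11.92 (17.04 to 17.4) and MT1F at 17.73 (21.33 to 22.01), and the unnumbered library had PGLYRP2 at 5.109 (6.202 to 6.401) and TBX3 at 325.8 (312.5 to 313.8).

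Among hypoxia DMSO libraries, replicate 1 had NR1I3 at 3.553 CPM (others 5.658 to 5.788) and MT1G at 4.279 (3.189 to 3.292), replicate 2 had HSPH1 at 92.6 (80.38 to 81.72), and replicate 3 had PGLYRP2 at 11.32 (9.08 to 9.378). With SLC-0111 in hypoxia, replicate 2 had GNRH2 at 27.72 (24.36 to 24.56). Replicate 4, the deepest library, had LGR5 at 54.86 (59.27 to 59.96), JUN at 512.8 (714.5 to 732.8) and BHLHE40 at 213.1 (299.9 to 305.7).

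The effect of SLC-0111 differed between hypoxia and normoxia, by the test of the difference, in 1102 genes and, at the preset correlation of camera, 19 lists. With an estimated correlation 0 lists were called, and fry called 8. Named genes with a positive difference in log2 were CA4 (0.65), DNAH10 (0.76), GPR161 (0.64), TGFB3 (0.60), CPB2 (1.30), PLK1 (0.38), MYBBP1A (0.36), HSPE1 (0.40), HSPB1 (0.33), GCM1 (1.38), SPRY4 (1), NR1D1 (1.18), APOH (0.63), LGR5 (0.63), CTSL (0.48), SQSTM1 (0.28), MT-ND4 (0.62), EPB41L3 (1.53), GPR83 (1.05), CENPA (0.33), NOTUM (0.75), HYOU1 (0.46), PDIA4 (0.46), TFEB (0.62), GPAM (0.81) and HSPH1 (0.35). Those with a negative difference were CA12 (−0.95), SLC7A11 (−0.63), PADI2 (−0.62), PGLYRP2 (−0.51), ABI3BP (−0.93), ABCC3 (−0.61), P4HA1 (−0.27), RNF223 (−1.22), B3GNT4 (−1.31), SYDE1 (−0.66), RNF183 (−1.03), MAB21L3 (−1.04), COL1A2 (−0.72), WDR54 (−0.61), PGK1 (−0.33), TNFSF10 (−1.77), NREP (−1.64), PLEKHA2 (−1.37), AQP1 (−1.35), STC2 (−1) and ALDH1L2 (−0.81). Of these calls that of HSPE1 was lost in 11 and that of CENPA in 9 of the 16 fits that leave out 1 library, both also with scaling by library size alone (adjusted p = 0.0523 and 0.0674), and that of HSPE1 with the protein-coding share as a covariate (0.0501). The call of NR1D1 was lost in 6 of these fits, with the covariate (0.0755) and with no filter on low counts (0.0686). Those of TFEB and SPRY4 were lost in 2 each of the fits that leave out 1 library, and that of PLEKHA2 in limma-voom (0.0701). TFEB (0.0679), HSPE1 (0.121) and CENPA (0.0502) were also lost on the 14 numbered libraries. Without hypoxia DMSO pairs, TFEB and CENPA were lost for 1 and 2, 2 and 3, 2 and unnumbered, and 3 and unnumbered. HSPE1 was lost for 1 and unnumbered, 2 and 3, 2 and unnumbered, and 3 and unnumbered. SPRY4 was lost for 1 and 2, 1 and unnumbered, and 2 and 3. NR1D1 (0.0556) and PLK1 (0.0528) were lost for 2 and 3.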

How the results depend on the processing

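The fits without pairs of hypoxia DMSO libraries, with the protein-coding share as a covariate, on nuclear protein-coding genes and on the 14 numbered libraries were chosen after the data were seen. Of the 6 pairs, 2 (1 and 3, and the other 2) were run first, picked from expression values, before all 6 were run. For the 11 counts of genes or lists, 319 alternatives stayed within 1.5 times the value reported and 23 did not. Where they did not, the cause was not tested, beyond the fewer libraries that some fits use.

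Leaving out each library in turn gave 3365 to 4947 calls for SLC-0111 in normoxia, 2238 to 3296 in hypoxia, 7912 to 9743 for hypoxia with DMSO, 7757 to 9250 with SLC-0111, and 1009 to 1347 genes in the overlap. The difference of the SLC-0111 effects moved most, from 691 without normoxia DMSO replicate 2 to 2040 without hypoxia DMSO replicate 1. With only the groups compared in the fit, SLC-0111 in hypoxia gave 1972 calls. Without hypoxia DMSO pairs it gave 1720 (1 and 2) and 1632 (1 and unnumbered), the overlap gave 850, 820 and 2135 (1 and 2, 1 and unnumbered, 2 and unnumbered), and the difference gave 2953, 524, 1738 and 640 (1 and 3, 2 and 3, 2 and unnumbered, 3 and unnumbered). With an estimated correlation 0 lists were called for SLC-0111 in normoxia, 0 in hypoxia, 1 for hypoxia with DMSO, 1 with SLC-0111 and 0 for the difference, and fry called 32, 28 and 8 in the last 3.

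The labels do not say that a replicate number marks a shared sample. Libraries numbered 4 varied together, those numbered 3 did not, and the data did not settle the pairing as a whole. Deviations from the group means correlated over 0.1 in 4 of 6 pairs of libraries numbered 1 (−0.03 to 0.178), 1 of 3 numbered 2, 0 of 6 numbered 3 and 3 of 3 numbered 4 (0.238 to 0.351), 8 of 18 in all. Of the 14 numbered libraries, 8 correlated best with a library of their own number. Between numbered libraries of different groups and numbers, most correlations lay under 0.1. The highest of these was 0.217, below that of every pair numbered 4. The unnumbered hypoxia DMSO library correlated at 0.176, 0.32 and 0.115 with the libraries numbered 4 of other groups. With those numbered 1 it correlated at −0.154, −0.252 and −0.06. The unnumbered normoxia SLC-0111 library correlated at −0.066 to 0.036 with libraries numbered 2 of other groups, and at −0.07 and −0.055 with those numbered 4. The fit without a block was set before the data were examined, and it takes no account of variation shared by libraries of the same number. The block on the 14 numbered libraries gave 4920, 3604, 8486 and 8616 calls in the 4 single contrasts and 1881 for the difference, where the same libraries without the block gave 3927, 2702, 7893, 8176 and 624.

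The fitted change of CA9 with SLC-0111 in normoxia, on 7 and 5 counts, ran from −0.770 without normoxia SLC-0111 replicate 1 to 0.798 without normoxia DMSO replicate 3 (log2). That of CA12 with SLC-0111 in hypoxia, which was not called, ran from −0.085 without hypoxia SLC-0111 replicate 1 to 0.042 without hypoxia DMSO replicate 2. It was 0.003 and 0.006 without hypoxia SLC-0111 replicates 3 and 4, and 0.099, 0.032 and 0.018 without the hypoxia DMSO pairs 1 and 2, 2 and 3, and 2 and unnumbered. Of the gene values with a library left out, 2627 kept direction and side of the threshold, 55 lost the call, 2 gained it and 4 turned. Calls lost in at least 1 setting were those of NPPB, MT-CO1 and ACTA2 with SLC-0111 in normoxia, and of ANKRD1, AKR1C2, BIRC5, CD14, CENPF, ASNS, MT-CO2 and CYP51A1 in hypoxia. So were those of PFKM in hypoxia with DMSO, and of HSPE1, CENPA, NR1D1, TFEB, SPRY4, PLK1 and PLEKHA2 in the difference. Hypoxia DMSO replicate 3, with 3.30 M counts, limits what can be said of low genes in that group.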

Other observations

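Several lists not described above were called in hypoxia with SLC-0111. Xenobiotic metabolism genes had 5 of 15 higher and 0 lower, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000467, and adjusted p = 0.177 with an estimated correlation). The inflammation list had 6 of 10 higher and 0 lower, or 7 and 0 adjusted over the list alone (adjusted p = 0.000107, and adjusted p = 0.0906 with an estimated correlation). Hypoxia with DMSO lowered 9 of 16 V-ATPase subunit genes and raised 1, or 10 and 1 adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.39 with an estimated correlation). With SLC-0111 present, hypoxia raised 14 of 20 WNT targets and lowered 4 in both counts (adjusted p = 0.000153, and adjusted p = 0.398 with an estimated correlation), and raised 7 of 10 progenitor and biliary markers and lowered 2 in both counts (adjusted p = 0.00429, and adjusted p = 0.24 with an estimated correlation). With DMSO, hypoxia raised 10 and lowered 8 of these WNT targets, and raised 7 and lowered 3 of these progenitor and biliary markers, over all genes.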
